A study of Homo sapiens with 2 samples.

How the data were processed

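NB4 cells were grown without a stated treatment and profiled by CUT&Tag with a PML-RARA antibody in 2 replicates, using a commercial kit and paired-end sequencing on a MiSeq, per the labels' protocols. The labels do not say whether the replicates came from separate cultures. Both replicates make up 1 group, and 1 merged peak list stands for them. Trimmomatic, Bowtie2, SAMtools, bedtools and the peak caller SEACR are named, with the build hg19, in the submitters' processing notes; versions, the threshold of SEACR, the use of a control track and the way the replicates were merged are not given in the sources used here.

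The deposited list gives for each peak a chromosome, a start, an end and a pair of signal columns that the authors took from SEACR. The column headed width in the deposited file is read here as SEACR's total signal and the column headed peak as its maximum signal: the former exceeds end minus start in all 20085 rows and never exceeds the length times the maximum. Both are whole numbers on the scale of summed coverage, and no source used here states a scaling to depth. The signal is the peak's own value from the authors and was used to describe, rank, filter, sum and compare peaks, all within this list. Peak length was taken as end minus start, and positions are printed as the list gives them; starts may count from 0, as in BED files. No peaks overlapped or were duplicated. No peak extended past the end of its hg19 chromosome (the highest end on chromosome 1 was 249219724 of 249250621), and on 14 chromosomes a peak lay past the last gene of the GRCh38 table.

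No hg19 genome sequence or full hg19 annotation was used here. The gene table at hand is on GRCh38, so it served for symbols, biotypes, gene counts per chromosome and placement of genes in GRCh38 cytogenetic bands, and none of its coordinates is printed. Reference data came from installed packages: cytogenetic bands of both builds from circlize 0.4.16, hg19 chromosome lengths from GenomeInfoDb 1.38.1, an hg19 gene-model sample from GenomicFeatures 1.54.1 (43 genes), and a gene-model sample (384 genes) and the CpG islands of chromosome X from pyranges 0.1.4. The samples are software examples, not random draws of genes. The pyranges tables do not name their build: on chromosome X, 9 of their 17 TSSs lay within 500 bp of an island, against 0 after a shift of 100 kb in either direction, and in the sample labelled hg19 it was 5 of 12 against 0. Together they gave 427 genes with 538 models; 16 of the genes repeat the TSS of another, and 31 of the 32 small RNA genes lie on chromosome 1.

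Peaks were placed in hg19 bands by their midpoints, genes in GRCh38 bands by theirs, and bands were matched by name, without converting coordinates. Of 784 bands other than centromeric, variable and stalk bands, 43 differed in length by more than 10% between the builds and were left out of tests that link genes to bands, which left 741. This exclusion was made after the list test had first been run with those bands kept (38 bands for the myeloid transcription factor list, mean log2 ratio 0.63, adjusted p = 0.0028 by the same random permutation of bands).

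The planned share of peaks at promoters and the planned list test on promoter peaks need a full annotation, so they were replaced by the share of sampled genes with a TSS peak and by a test of the bands that hold each list's genes. A peak counted for a gene if it overlapped the 2 kb on either side of any of its TSSs. Random placements kept the lengths and chromosomes of the peaks, avoided centromeric, variable and stalk bands, and were drawn 1000 times. For each list, peaks per Mb (with 0.5 peak added) in each band that holds a member was divided by the median of bands in the same class of gene density (10 classes of equal size), and the mean log2 ratio was compared with 10000 sets of random bands from the same classes. The 14 lists, with 354 genes, were fixed before the data were examined, as were the rule for named genes and the first set of alternatives; 330 of the genes lay in the bands used. T and B lymphocyte, neuronal and hepatocyte markers were included as markers of other cell types. Peak signals were compared by permuting 100000 times, correlations across bands or chromosomes likewise, stain classes 10000 times, and bootstrap intervals used 2000 draws. A run of peaks joins neighbours with gaps of at most 10 kb. The tests on sampled genes and on bands, the stain test, the coverage profile, the biotype comparison, the correlation across bands and the count at CpG islands were chosen after the file had been seen.

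The rule for named genes takes PML and RARA, the genes of the 10 peaks with the highest total signal on chromosomes 1 to 22 and X, up to 4 members of each list with the strongest promoter peaks, and the 3 loci with the most peaks. Without a full annotation, the second part was met by the listed genes in the peak's band and the third by the 6 list members among the sampled genes. The third of the loci with the most peaks is not reported here. Other genes and bands in the text were chosen after their values were seen.

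The p-values describe how the peaks of this 1 merged list are arranged, not the spread between cultures, and intervals on shares cover counting error only. The depth is unknown, so a locus without a listed peak can lie below the authors' threshold, and the lowest total signal in the list was 2577. The tests were tested on simulated data. With peaks placed at random, the TSS test gave p under 0.05 in 9 of 100 runs, and with peaks set on 60 TSSs it did so in 20 of 20. For the list test, simulations without an effect shuffled band densities within the gene-density classes from which it draws random bands. They meet its own assumption by construction and cannot show how often it errs on real bands. In them the list test, on the 734 matched bands that hold a protein-coding gene, made 0 calls in 280 tests. With adjustment over all lists, as in the analysis, it found a list raised 2-fold in 20 of 20 runs and 1.5-fold in 7 of 20, so a rise of the smaller size can stay uncalled (15 of 20 for that list alone, at an unadjusted permutation p under 0.05). The chromosome test found a 1.3-fold excess on chromosome 20 in 20 of 20 runs. Those runs drew peaks as independent counts, which the test assumes, so they do not cover peaks that gather at loci. No simulation without an effect was made for the chromosome test, so its rate of false calls is unknown. Alternatives covered the peak filter, the window, the signal measure, the random placement, the way runs of peaks and shared TSSs are counted, the expectation per chromosome and the choice of bands. Motif counts (23 consensus sequences) and the nearest gene of each peak were left out for want of an hg19 sequence and annotation. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.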

Results

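NB4 is a human acute promyelocytic leukemia cell line that carries the PML-RARA fusion, in which the nuclear body protein PML is joined to the retinoic acid receptor alpha, RARA. DNA under proteins bound by a PML-RARA antibody was profiled with CUT&Tag, an assay in which a transposase tethered to an antibody inserts sequencing adapters into the chromatin next to the antibody. The series held 2 replicates of 1 group, cells with no stated treatment, and 1 peak list merged from both by the authors. The question was where in the genome of NB4 cells the antibody signal lies. No second group, control antibody or input library was analysed here, the sequencing depth is unknown, and the list carries no value per replicate, so no spread between replicates can be given.

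The antibody signal lay in 20085 peaks that together covered 23708 kb, a length equal to 0.781% of hg19 chromosomes 1 to 22 and X. Of the peaks, 20072 lay on chromosomes 1 to 22 and X and covered 0.779% of them. Another 13 lay on contigs that are unplaced or not localised, and none was listed on chromosome Y or the mitochondrial genome. The median peak was 893 bp long (interquartile range 660 to 1337 bp), and 2206 peaks were longer than 2 kb. The authors' total signal per peak, read here as the coverage summed over its bases, had a median of 6479 (interquartile range 3755 to 13912) and reached 876984. The top 10% of peaks held 46.6% of the summed signal, and the top 1% held 13.4%.

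By total signal the strongest peak of the list stood in band 19p13.2, on the short arm of chromosome 19. The peak at chromosome 19, 8553961 to 8574679, was the longest (20718 bp) and had the highest total signal on the chromosomes (876984) and a maximum of 830. It was flanked by peaks at 8549738 to 8553836 (total 307911, maximum 773) and at 8575201 to 8585121 (total 325007). Between 8454419 and 8813735, a stretch chosen after its values were seen, this band held 59 peaks with a summed signal of 3062954, which was 1.11% of the signal on the chromosomes. A further peak of this band, at 10675743 to 10680720, had a total of 398272.

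**Figure D1:**
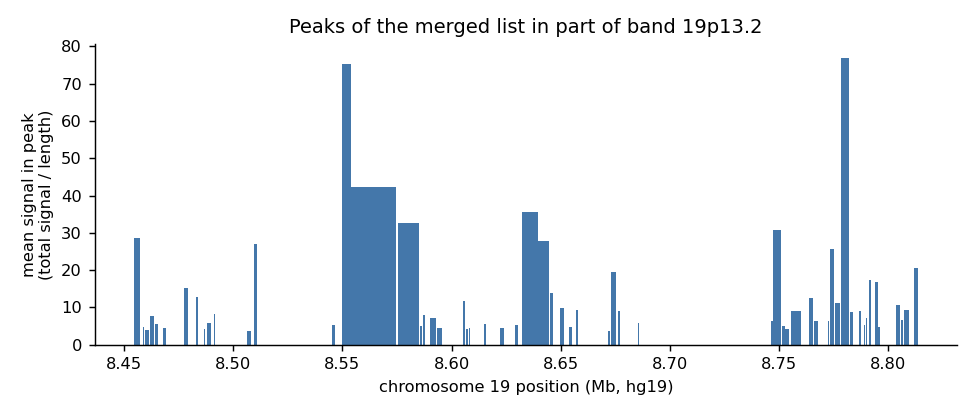
Peaks of the merged list in part of band 19p13.2, with the position on chromosome 19 in Mb (hg19) on the horizontal axis and the mean signal per base of each peak (total signal divided by length) on the vertical axis. Each bar is 1 of 59 peaks, drawn over its own start and end; the broad block at 8553961 to 8574679 is the peak with the highest total signal.

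The other 8 of the 10 peaks with the highest total signal lay in 8 different bands, several of which also hold genes of the lists fixed beforehand. Band 17q22, which holds MPO, the gene of the neutrophil enzyme myeloperoxidase, had a peak at chromosome 17, 56401454 to 56417675, with a total of 553145. Band 5q31.2, which holds the zinc finger factor gene EGR1, had a peak at chromosome 5, 139037929 to 139051551, with a total of 406954. Band 1p36.11, which holds the hematopoietic transcription factor gene RUNX3, had a peak at chromosome 1, 26604268 to 26618840, with a total of 358310. Band 6p21.1, which holds CCND3, a D-type cyclin gene, and RUNX2, had a peak at chromosome 6, 41902115 to 41910184, with a total of 337697. Band 7q11.23, which holds NCF1, a subunit of the phagocyte NADPH oxidase, had a peak at chromosome 7, 73129273 to 73134701, with a total of 346190. In 19q13.33, which holds BAX, RPL18 and SLC17A7, the peak at chromosome 19, 49135604 to 49143458, reached a total of 426858. The remaining peaks, at chromosome 10, 104401665 to 104409271 (10q24.32, total 347586) and 102819778 to 102827905 (10q24.31, total 335086), lay in bands without a listed gene. The genes are named by shared band alone: the distance from peak to gene was not measured, and gene links of 19p13.2 were not made because that band's length differs between the builds. The share of all peaks that lie in bands with a listed gene was not set beside these bands. Their listed genes are therefore no sign of a link between strong peaks and the lists.

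Peaks gathered in runs. Of the 20072 peaks on the chromosomes, 12317 (61.4%) had a neighbour within 10 kb, against 4011 ± 70.1 (mean and SD of 1000 random placements of the same peak lengths on the same chromosomes), a ratio of 3.07 (one-sided permutation of positions, p = 0.000999, the smallest that 1000 placements can give). The run with the most peaks lay in 19p13.2, at chromosome 19, 10360818 to 10547377, with 39 peaks and a summed signal of 1704921. The next lay in 16q24.3, at chromosome 16, 88742578 to 88888263, with 38 peaks, in a band that holds the transcriptional co-repressor gene CBFA2T3 with RPL13 and TUBB3. In all, 1735 runs of at least 3 peaks held 8825 peaks (44.0%). The ratio was 1.80 when peaks were placed at random within their own cytogenetic band and 1.46 with neighbours counted within 50 kb. Pieces of 1 broad stretch that are listed as separate peaks count as neighbours here. Merging peaks within 1 kb left 17149, and the neighbour count was not repeated on the merged peaks.

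Both partners of the fusion lay in bands with many peaks. The band of PML, 15q24.1, had 52 peaks, or 20.8 per Mb, which ranked 85 of 784 bands, and the band of RARA, 17q21.2, had 66 peaks, or 26.4 per Mb, which ranked 53. Relative to the median of bands with a like density of protein-coding genes, these were 1.42-fold and 1.15-fold. The strongest peak of 15q24.1 lay at chromosome 15, 75068971 to 75078334 (total 206540, rank 55 of the peaks on the chromosomes). The strongest of 17q21.2 lay at chromosome 17, 38476060 to 38481245 (total 75785, maximum 117, rank 433). No test was made of these bands, and the position of either gene within its band was not used.

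Transcription start sites (TSSs) carried peaks far more often than random positions. Of 427 genes with an hg19 TSS in the gene models used, 176 (41.2%, 95% Wilson interval 36.6 to 45.9%) had a peak within 2 kb, against 19.2 ± 4.47 genes (mean and SD, highest 35) in 1000 random placements, a ratio of 9.16 (one-sided permutation of positions, p = 0.000999, the smallest that 1000 placements can give). Protein-coding genes had one in 154 of 329 cases (46.8%), long noncoding RNA genes in 16 of 49 (32.7%) and small RNA genes in 4 of 32 (12.5%). Two-sided Fisher's exact tests, adjusted over both comparisons, set protein-coding genes apart from small RNA genes (odds ratio 6.16, adjusted p = 0.000252) and not from long noncoding RNA genes (odds ratio 1.82, adjusted p = 0.0666). Some gene models share a TSS, so the genes are not all separate sites: with each shared TSS counted once, small RNA genes had a peak at 4 of 21 TSSs and protein-coding genes at 153 of 328, an odds ratio of 3.72 (exact test, adjusted p = 0.0431). Peaks covered 28.4% of bases in the 500 bp upstream of the TSS (95% bootstrap interval over genes 24.5 to 32.2%) and 28.1% in the 500 bp downstream, 36.4 and 36.1 times the share of the chromosomes that lies in peaks. Coverage fell to 2.44% at 20 to 50 kb downstream, still 3.14 times that share. Within 2 kb, coverage downstream exceeded coverage upstream by 0.557 percentage points ± 0.960 (SE over 427 genes), a difference that a two-sided sign-flip permutation test did not separate from 0 (p = 0.562).

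**Figure D2:**
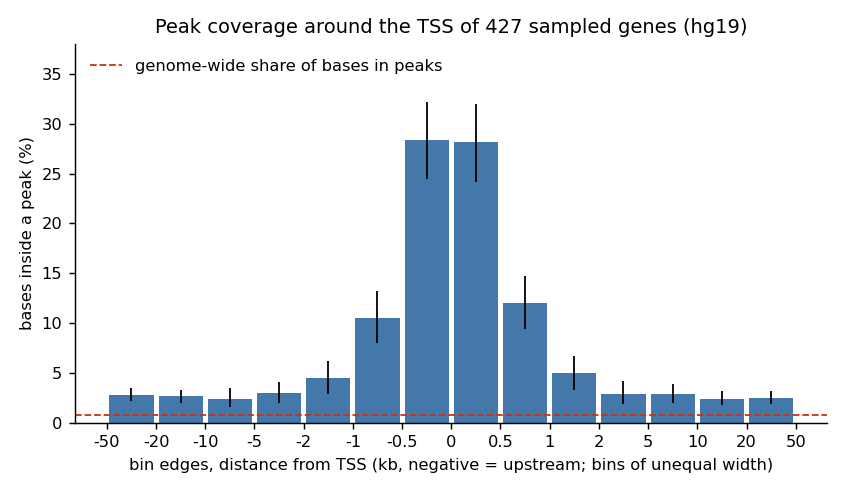
Share of bases inside a peak (%, vertical axis) in bins of distance from the TSS (kb, negative is upstream, bins of unequal width) over 427 genes. Bars are means over genes, lines are 95% bootstrap intervals over genes and the dashed line is the share of the chromosomes in peaks, 0.779%; the bins on either side of the TSS reach 28.4% and 28.1%.

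Among these genes, 6 belonged to the fixed lists. GAPDH, a glycolytic enzyme of the housekeeping list, had a peak over its TSS at chromosome 12, 6641189 to 6645714, with a total of 66182 (rank 565). ETV6, a hematopoietic repressor of the ETS family, had its nearest peak 145 bp from the TSS with a total of 9577. S100A9, a subunit of neutrophil calprotectin, had one 1859 bp away with a total of 3244. ALDH1A3, a retinaldehyde dehydrogenase, HDAC9, a histone deacetylase, and the neuronal gene MAP2 had none within 2 kb, and their nearest peaks lay 38142, 554874 and 590527 bp away.

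Other genes were named after their values were seen. The strongest TSS peaks belonged to ADAM8, a membrane metalloprotease of leukocytes (chromosome 10, 135086009 to 135094595, total 254232, rank 30), and to FKBP5, a co-chaperone of steroid receptors (chromosome 6, 35693161 to 35700751, total 118752). They were followed by DYNLT4 (total 106682) and CTTN, which encodes the actin-binding protein cortactin (total 77574). KEAP1, the adaptor that directs NRF2 to degradation, had a TSS peak of total 52744, and XPO1, the nuclear export receptor, one of 46996. RELT, a member of the TNF receptor family, had 31571, NFKB2, a subunit of NF-kappaB, 17469, LTA4H, an enzyme of leukotriene synthesis, 16659, and IL6ST, a signal transducer of interleukin receptors, 6610. TLR2, a receptor for bacterial lipoproteins, had its nearest peak 217177 bp away, and those nearest to the hair keratin gene KRT85 and the olfactory receptor gene OR2K2 lay 62100 and 154304 bp away. A TSS peak may also serve a neighbouring gene that the models leave out, and 144 of the 427 genes (33.7%) lie on chromosome 1, so the share holds for these genes and is no estimate for the genome. The ratio was 13.9 with a window of 1 kb, 4.78 with 5 kb and 3.05 with 10 kb, and 4.96 when peaks were placed at random within their own band.

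Peaks at the sampled TSSs had more total signal than the other peaks. The median was 8172 in 207 peaks within 2 kb of a sampled TSS and 6459 in 19865 others, a ratio of 1.27 (95% bootstrap interval 1.05 to 1.43, two-sided permutation p = 0.00759). A longer peak is more likely to overlap the window, and total signal rose with peak length (Spearman's rho 0.805). The median length was 942 bp at sampled TSSs and 892 bp in the others, and the permutation did not hold length fixed. It cannot tell more signal at TSSs from this effect of length. The difference in median log10 total signal was 0.102, and for the height of the peaks no difference was separated from 0. The median maximum was 23 against 22 (log10 difference 0.0193, permutation p = 0.714, 95% bootstrap interval of the ratio 0.955 to 1.18). The median signal per base was 8.10 against 7.52 (0.0321, permutation p = 0.119, interval 0.980 to 1.17). Both intervals overlap that of total signal, and no test compared the measures. The other peaks include any at TSSs outside the gene models used, which may move the groups together, and this was not measured.

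Bands that hold genes of myeloid and hematopoietic transcription factors had more peaks than bands of like gene density. Over the 35 bands of this list, peaks per Mb averaged 1.53-fold the median of like bands (mean log2 ratio 0.61, SD over bands 1.28), and 26 of the 35 lay above that median. Among 10000 random sets of like bands the mean was -0.09 ± 0.19 (SD), which gave a two-sided p of 0.0002, the smallest these sets can give, and an adjusted p of 0.0028 by the Benjamini-Hochberg method over 14 lists. With any 1 band left out the mean log2 ratio stayed between 0.53 and 0.70. The mean exceeded that of the ribosomal protein and housekeeping list by 0.363, with a 95% bootstrap interval of -0.129 to 0.876 that includes 0. The band of MYC, 8q24.21, had 25 peaks, or 5.95 per Mb, fewer per Mb than the band of IRF8 (42.8). With 6 protein-coding genes it was set against bands of low gene density, and by fold it stood highest at 9.96-fold. It was followed by the bands of IRF8, a factor of monocyte and granulocyte fate (16q24.1, 124 peaks, 5.54-fold), ID2, an inhibitor of helix-loop-helix factors (2p25.1, 86 peaks, 4.94-fold), and IKZF1, a lymphoid zinc finger factor (7p12.2, 13 peaks, 4.76-fold). MEIS1 (2p14, 4.71-fold), CEBPB (20q13.13, 4.04-fold), RUNX1 (21q22.12, 4.01-fold) and CBFA2T3 (16q24.3, 3.94-fold) came next, and the lowest were the bands of HHEX (10q23.33, 0.42-fold), TAL1 (1p33, 0.25-fold) and ETV6 (12p13.2, 0.18-fold).

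The other 13 lists did not pass the test, with adjusted p from 0.392 to 0.903. On the higher side, the 8 bands of the NADPH oxidase averaged 1.43-fold with 7 above the like median, led by the band of CYBA (16q24.2, 2.65-fold). The 30 bands of ribosomal protein and housekeeping genes averaged 1.19-fold with 18 above, the 20 of neuronal markers 1.19-fold with 15 above, and the 15 of PML nuclear bodies and the SUMO pathway 1.17-fold with 11 above, among them those of PIAS1 (15q23, 2.79-fold) and RNF4 (4p16.3, 2.19-fold). Neutrophil granule proteins averaged 1.13-fold with 10 of 17 bands above, including that of SRGN (10q22.1, 2.26-fold). Co-repressor and chromatin-modifying complexes averaged 1.06-fold with 15 of 27 above, including that of HDAC4 (2q37.3, 2.96-fold), and interferon response genes 1.04-fold with 6 of 13 above. On the lower side, cell cycle and apoptosis genes averaged 0.97-fold with 11 of 25 above, coagulation and fibrinolysis genes 0.89-fold with 3 of 14 above in spite of 7.02-fold in the band of F13A1 (6p25.1), and T and B lymphocyte markers 0.81-fold with 6 of 19 above. Myeloid surface receptors averaged 0.78-fold with 7 of 22 above, hepatocyte markers 0.74-fold with 7 of 20 above, and retinoid receptors and retinoid metabolism 0.72-fold with 11 of 23 above. In that last list the bands of ALDH1A3 (15q26.3, 2.93-fold) and CYP26B1, a retinoic acid hydroxylase (2p13.2, 2.03-fold), stood highest, ahead of those of RXRA (9q34.2, 1.69-fold) and RARG (12q13.13, 1.69-fold). Its lowest were LRAT (4q32.1, 1 peak, 0.13-fold), NRIP1 (21q21.1, no peak, 0.11-fold) and RARRES1 (3q25.32, no peak, 0.07-fold). Without a peak the value rests on the 0.5 peak added, and such bands weigh heavily on the mean. With 1 band left out the mean log2 ratio of -0.47 rose to as much as -0.32, so the average does not show a broad deficit. For myeloid surface receptors, whose lowest band was Xp22.33 (1 peak, 0.10-fold), the mean of -0.35 likewise rose to as much as -0.21. A band holds many genes, so these values describe neighbourhoods of several Mb and assign no peak to a gene; the bands named here were chosen after their values were seen.

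**Figure D3:**
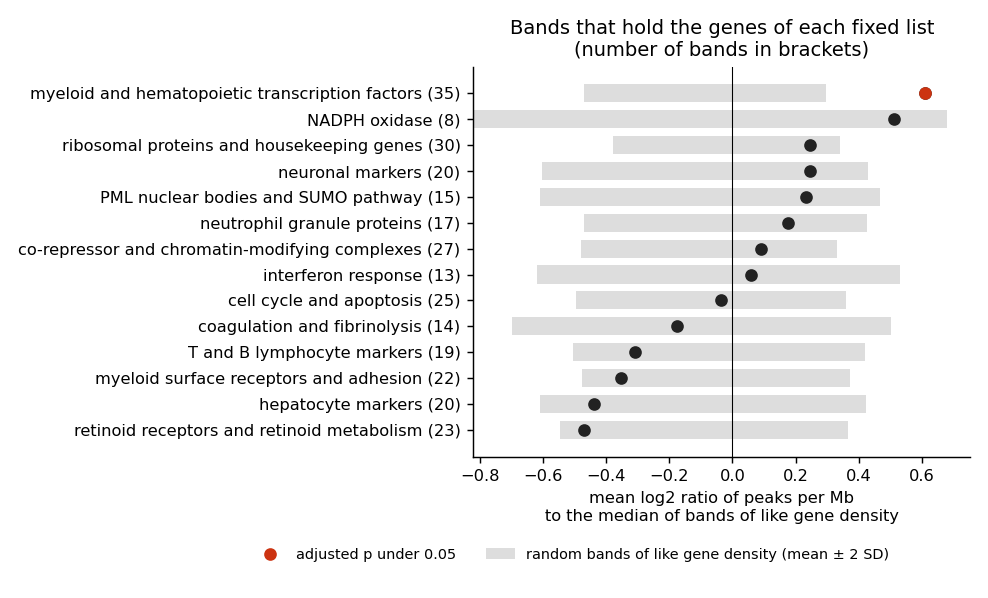
Mean log2 ratio of peaks per Mb to the median of bands of like gene density (horizontal axis) for the bands that hold the genes of each of 14 lists (vertical axis, number of bands in brackets). Points are the lists, grey bars span the mean ± 2 SD of 10000 random sets of like bands, and the red point, at 0.61, is the list with an adjusted p under 0.05.

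Peaks followed the gene-rich, pale-staining part of the chromosomes. Giemsa-negative bands held 14048 peaks at 10.9 per Mb (95% bootstrap interval over bands 9.64 to 12.2) and the palest positive class 2703 at 12.5 per Mb (9.16 to 16.6), while the darkest class held 496 at 0.995 per Mb (0.748 to 1.27). Pale bands together had 4.45 times the density of the darker ones (3.66 to 5.38, two-sided permutation p = 0.0002, the smallest that 10000 permutations can give), and 1.81 times as many peaks per protein-coding gene. Across 741 bands, peaks per Mb rose with protein-coding genes per Mb (Spearman's rho 0.795, Pearson's r 0.732, permutation p = 1e-05 for each, the smallest possible); neighbouring bands are not independent replicates. The densest of these bands were 11q13.1 with 227 peaks (90.8 per Mb) and 16q24.3 with 150 (90.6 per Mb), against a median of 3.45 per Mb, and 63 had no peak listed.

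**Figure D4:**
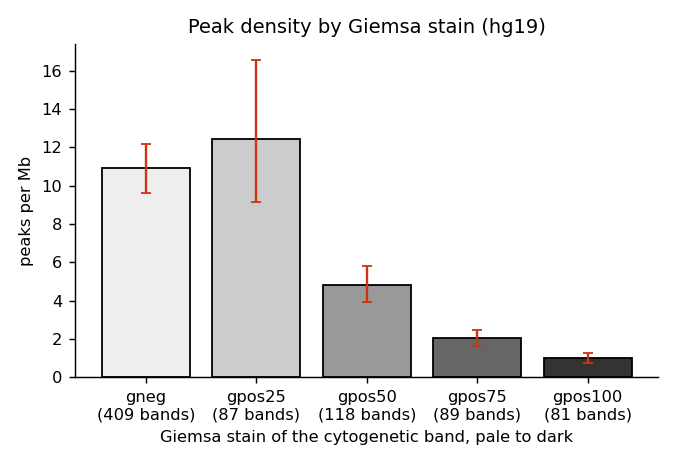
Peaks per Mb (vertical axis) in cytogenetic bands grouped by Giemsa stain from pale (gneg) to dark (gpos100), with the number of bands in brackets. Bars are pooled densities and red lines 95% bootstrap intervals over bands; the density runs from 10.9 and 12.5 per Mb in the palest classes to 0.995 in the darkest.

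Chromosomes differed in peaks per protein-coding gene. Chromosome 20 had 852 peaks against 540 expected from its share of protein-coding genes, a ratio of 1.58 (95% exact binomial interval 1.48 to 1.69), followed by chromosomes 16 (1.34), 10 (1.29) and 22 (1.27). Chromosome X had 379 against 852 expected, a ratio of 0.445 (0.401 to 0.491), and chromosomes 4, 8 and 18 had 0.707, 0.708 and 0.744. In two-sided exact binomial tests with Benjamini-Hochberg adjustment over 23 chromosomes, 12 had more and 8 fewer peaks than expected from protein-coding genes. Against the number expected from chromosome length, 8 had more and 11 fewer, led by chromosome 19 with a ratio of 4.09; 13 chromosomes were called on the same side both ways, and chromosomes 1 (0.838 to 1.05), 2 (1.10 to 0.861) and 9 (1.08 to 0.907) were called on opposite sides. These tests treat each peak as independent; with each run of peaks counted once, 10 were higher and 8 lower, 15 were called on the same side both ways, and chromosome 19 turned from 1.10 to 0.851. The copy number of each chromosome in NB4 cells was not removed from these counts, since no input library was used here.

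**Figure D5:**
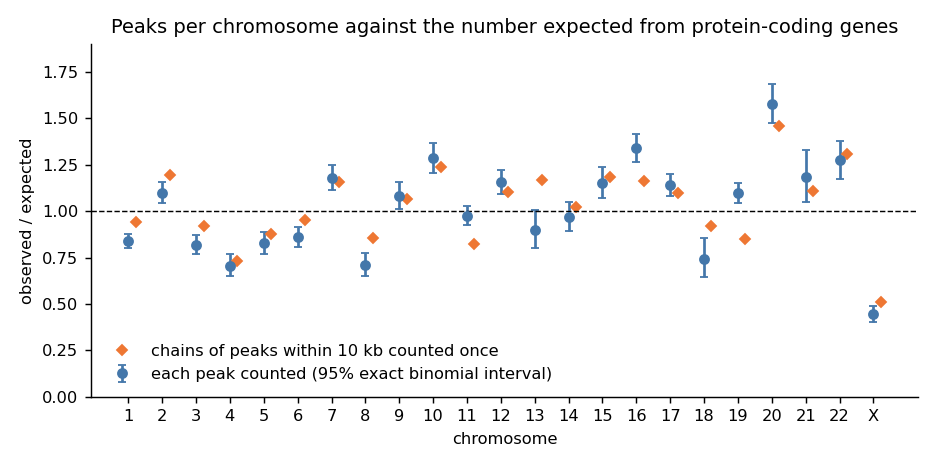
Observed over expected number of peaks (vertical axis) for each of 23 chromosomes (horizontal axis), with the expectation from each chromosome's share of protein-coding genes. Blue points count each peak, with 95% exact binomial intervals that cover counting error only, and orange diamonds count each run of peaks within 10 kb once; chromosome 20 stands highest (1.58) and X lowest (0.445).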

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

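The test in this part was chosen after its result had been seen. A signal stood outside the chromosomes on which the comparisons rest: 13 peaks lay on contigs that are unplaced or not localised, with no control library to set them against. By total signal the strongest lay on the unplaced contig chrUn_gl000220 at 119442 to 138428 (290974 over 18986 bp), followed by one on chr7_gl000195_random at 30208 to 33471 (272501). The neighbour of the former, at 117307 to 119219, had a total of 265419 and the highest maximum signal of the whole list (1005). Of the technical explanations, multi-copy sequence that the build holds in 1 copy may raise such peaks. The median signal per base of the 13 peaks was 2.04 times that of peaks on the chromosomes (95% bootstrap interval 1.04 to 5.71). The ratio itself met the bound of 2-fold for this explanation, but that bound was set after the result was seen. The interval reaches below it, and several of the 13 peaks adjoin on chrUn_gl000220 and are not separate sites. The test therefore leaves this open. Reads that the aligner could place in several copies, and SEACR's treatment of them, stay untested, and no biological explanation was tested because the design has 1 group.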

How the results depend on the processing

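The alternatives added after the data were seen are named near the end of this part. With the peaks at or above the median total signal the list held 10043 peaks and with the top 10% 2009, by the construction of these filters; merging peaks within 1 kb left 17149. Of the tests of the peaks as a whole, the signal of promoter peaks was the one that lost its call: the log10 difference of 0.102 was 0.0193 for maximum signal and 0.0321 for signal per base, and the cause was not tested. For the other such tests the alternatives that were run kept direction and side of the threshold: the TSS ratio ranged from 3.05 to 13.9, clustering from 1.46 to 4.24, the stain ratio from 1.81 to 5.90, and the odds ratio of protein-coding against small RNA genes from 3.72 to 6.16 (5.47 on chromosome 1 alone). Single chromosomes did not: 18 to 20 were called, but with the expectation from length 1 (1.05), 2 (0.861), 9 (0.907) and 21 (0.893, no longer called) changed direction, as did 19 with runs counted once (0.851). Calls were also lost by chromosomes 7, 10 and 15 by length, by 6, 9, 18 and 21 with runs counted once and by 9, 15 and 22 with peaks at or above the median signal. Newly called were 11 (1.43), 13 (0.401) and 14 (0.829) by length, 11 (0.825) and 13 (1.17) with runs counted once, and 13 (0.836) at the median filter, against 0.976, 0.898 and 0.967 for 11, 13 and 14 before. Uncalled on both occasions, 11 rose above 1 at the median filter (1.03) and 14 with runs counted once (1.02). Chromosomes 3, 4, 5, 8, 12, 16, 17, 20 and X stayed called on the same side in all 3 alternatives. The closest of these to the threshold was 3 with runs counted once (0.917, exact binomial test, adjusted p = 0.0482). The myeloid transcription factor list was the one list called in each of 6 alternatives (mean log2 ratio 0.41 to 0.85, adjusted p 0.0028 to 0.0112), and the other lists stayed uncalled in each, though the cell cycle, interferon and co-repressor lists, with means near 0, changed sign in some. Added after the data were seen were the placements within bands, protein-coding genes alone, omission of chromosome 1, shared TSSs counted once, runs counted once, expectation from length, total signal per Mb, bands kept, stain matching, the stain alternatives and other peaks within 50 kb (0.0978, permutation p = 0.0418, with a 95% bootstrap interval of -0.000127 to 0.174 that includes 0). Not run were the motif alternatives, the nearest-gene assignment and the promoter windows for lists, for want of an hg19 sequence and annotation. No paired analysis was possible because there is 1 group and the list is merged, and for the same reason neither replicate could be left out. Depth is unknown, so weak sites are limited by the authors' threshold.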

Other observations

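On chromosome X, which had the fewest peaks per gene, many of the listed peaks overlapped CpG islands; this count was chosen after the file had been seen. Of 379 peaks on X, 189 (49.9%, 95% Wilson interval 44.9 to 54.9%) overlapped an island, against 4.14 (1.09%) in 1000 random placements, a ratio of 45.7 (one-sided permutation of positions, p = 0.000999, the smallest possible). Conversely, 182 of the 896 islands of X (20.3%) had a peak. The median total signal was 7178 at islands and 5446.5 elsewhere, a difference that was not tested. Band Xp22.33, which holds the cytokine receptor genes IL3RA and CSF2RA, had 1 peak, and Xp21.1, which holds the oxidase gene CYBB, had 1. Whether reads from Xp22.33 could also be placed on chromosome Y was not examined.

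Several of the tallest peaks lay outside the 10 with the highest total signal. The peak at chromosome 12, 26426551 to 26429411 (12p12.1) was 2860 bp long and had a maximum of 693 and a total of 292362. A peak at chromosome 16, 85088062 to 85090486, in the band of IRF8 (16q24.1), had a maximum of 532 and a total of 137535, and one at chromosome 5, 959809 to 965285, in the band of the telomerase gene TERT (5p15.33), had a maximum of 527 and a total of 265761. In 14q11.2, which holds the granulocytic factor gene CEBPE and the eosinophil ribonuclease genes RNASE2 and RNASE3, the peak at chromosome 14, 23581480 to 23590490, had a total of 305394. The band as a whole had 0.64-fold the peaks per Mb of like bands. These bands were chosen after their values were seen.

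The tests of hypotheses that follow were written before their results were seen. The excess in gene-dense bands and at TSSs may reflect open chromatin in general, which a transposase enters with any antibody, rather than the fusion protein at myeloid genes. If so, bands of myeloid transcription factor genes should exceed those of housekeeping genes by no more than 0. The difference in mean log2 ratio was 0.363 with a 95% bootstrap interval of -0.129 to 0.876, which includes 0. A clear difference above 0 would not have decided it either. In a promyelocytic line, open chromatin may itself be richer around myeloid genes, and openness was not measured. The explanations therefore cannot be told apart by this test. Without a control antibody the share of either stays open.

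Unequal peaks per gene between chromosomes may come from chromosome copy number in NB4 cells, which would let peaks be more numerous where signal is higher. Across 23 chromosomes the ratio of observed to expected peaks instead fell as the median signal per base rose (Spearman's rho -0.430, permutation p = 0.0417, adjusted over 2 relations 0.0834; Pearson's r -0.437, permutation p = 0.0365). By the unadjusted p this met the bound written beforehand against copy number. It is not read as excluding it, because that p does not hold after adjustment, r drops to -0.297 without chromosomes 22 and 16, and a list with a minimum total signal admits more weak peaks where signal is higher, which can lower the median; this reading was chosen after the result was seen. The Giemsa-negative share of a chromosome's length showed no relation that the test could detect (rho 0.0119, permutation p = 0.958, adjusted 0.958; r 0.0439, permutation p = 0.844, and 0.0616 without chromosomes 17 and 21), so both explanations stay open, and no biological explanation was tested.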
